A study of Drosophila melanogaster with 48 samples.

How the data were processed

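RNA from Drosophila melanogaster wing imaginal discs and developing wings was measured on 48 Affymetrix Drosophila Genome 2.0 arrays. Per the labels' protocols, the animals carried a UAS transgene for Ubx (isoform Ia) or, as control, for eGFP, together with a Gal4 driver inserted in nab and a temperature-sensitive Gal80 repressor. The transgene was off at 19 °C and was switched on by moving animals to 29 °C for 16 h. Tissue was taken from larvae, prepupae and pupae, with 4 biological replicates of each line at each stage and temperature, which makes 12 groups. Each sample pooled about 15 to 20 animals and 2 µg of RNA was labelled. Prepupae were taken 12.5 h after puparium formation at 19 °C or 6 h after it at 29 °C, and pupae 33.5 h or 16 h after it, respectively. Larvae were staged by gut colour.

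The deposited table holds log2 values made by the authors with RMA (background correction, quantile normalisation and summary per probe set), per the submitters' processing notes. The RMA version and the log base are not given in the sources used here; the log base was taken from the range of the values, 2.37 to 14.6. Distributions of the deposited values coincided within each set of 8 arrays of a stage and temperature (largest distance 0.0658) and differed between the 6 sets (smallest distance 0.138), so normalisation appears to have been run per set. Ubx and eGFP arrays that are compared lie in the same set. Comparisons of temperatures or stages cross sets, and for these the set and the condition cannot be told apart.

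All of the 48 value columns were matched to a sample label. Of 18952 probe sets, 183 array controls were left out and 18769 were tested. Gene names came from the supplied annotation of the probe sets, in which 13647 tested probe sets had 1 symbol, 402 had several and 4720 had none. Symbols covered 11982 genes, of which 1094 had more than 1 probe set. Probe sets with several symbols were counted but not named.

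A linear model with a mean per group was fitted to the log2 values of all 48 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. It had 36 residual and 5.16 prior degrees of freedom. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the probe sets of a contrast, and a call required an adjusted p under 0.05. Contrasts were Ubx against eGFP at each temperature and stage, the interaction of line with temperature, the change between stages of the line difference at 29 °C (that at 19 °C not subtracted), and, in the eGFP line, the temperatures and the successive stages at 19 °C. A probe set called at 29 °C and in the interaction in the same direction is termed Ubx-dependent. Differences are Ubx minus eGFP on the log2 scale unless stated, with the standard error (SE) of the model and 4 arrays per group. The number of arrays limits their precision. No detection calls were available, so a group mean under or near the array medians was not taken as shown to be above background; the margin of 0.5 for this was chosen after the values were seen.

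Groups, contrasts, thresholds, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule named nab and Antp, the 10 Ubx-dependent genes with the largest rise and the 10 with the largest fall per stage (at least a 1.5-fold change), up to 4 called members per gene list, and the 5 largest rises and falls in the other comparisons. Some genes known only by a CG number were not printed. A gene was read through its probe set with the highest mean over all arrays. Where probe sets of a gene disagreed in call or sign this is stated.

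The gene lists numbered 26, with 470 of 596 members measured. Some genes belong to several lists, so the results of lists are not independent. A member was matched by its current symbol, or by a synonym only where the listed name is no gene's current symbol and the synonym belongs to a single gene. A list of transgene and line markers had too few measured members to test, and Ubx itself, w, wg, N and Dl, which no probe set names, were not analysed here. The other 25 lists were tested against all other genes with camera in limma, with a preset correlation between genes of 0.01, and again with a correlation estimated from the data. Overlaps were tested with Fisher's exact test in R. The remaining tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

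The procedure was tested on simulated data with the real spread of each probe set and 100 of 18769 probe sets changed per fold size. Group means were the real ones, but at the tested stage the Ubx line was first given the means of the eGFP line. At 1.5-fold, the share called at 29 °C was 97 percent for larva, 95 percent for prepupa and 92 percent for pupa. The share recovered as Ubx-dependent was lower, at 89, 90 and 83 percent. False calls made up 3, 4.9 and 5.9 percent of the calls. Noise was drawn independently for each probe set, so these shares do not cover variation that probe sets of an array have in common.

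Alternatives tried were centring each array on its median, quantile normalisation over all arrays, leaving out the dimmest 40 percent of probe sets, 1 probe set per gene, a fold threshold, another variance model, the arrays of the named stages alone, a replicate block, leaving out each array in turn, and for lists the mean of a gene's probe sets. Other splits of the arrays were compared with the real grouping, up to 100 of them drawn with seed 20110.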

Results

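The data compare wing tissue expressing Ubx, the Hox gene that sets the haltere apart from the wing, with wing tissue expressing eGFP at 3 stages, and ask which genes respond at each. Each of the 12 groups held 4 arrays, 48 in all. Array medians ran from 4.18 on a pupal array at 19 °C to 4.76 on a prepupal array at 29 °C. The lowest correlation between replicate arrays, taken across probe sets, was 0.995.

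The first comparison asked what Ubx changes in the larval wing disc. The homeobox gene Dll fell by 1.07 (SE 0.07, adjusted p = 5.32e-15) and the T-box genes Doc1 and Doc2 fell by 1.17 (SE 0.09, adjusted p = 5.08e-14) and 1.03, all of them used in patterning the appendage. The gene for the secreted protein larval translucida, ltl, fell by 1.56 (SE 0.09, adjusted p = 9.55e-17). Among cuticle genes, Vajk3 fell by 2.47 and TwdlE by 1.03, while Cpr72Ea rose by 0.92 (SE 0.07, adjusted p = 1.36e-12). The transcriptional cofactor gene nab, in which the driver sits, rose by 0.71 (SE 0.07, adjusted p = 3.01e-09), with a difference of 0.08 at 19 °C. The ecdysone-induced receptor gene Hr3 rose by 1.24 (SE 0.34, adjusted p = 0.028). The cytochrome gene Cyp4p1 fell by 4.15, against -3.35 at 19 °C. Other large changes were those of CG7201, which fell by 2.35, CG10311, which fell by 1.28, CG6701, which fell by 1.03, and CG13024, CG10019 and CG3036, which rose by 1.05, 0.78 and 0.77. CG17124 rose by 0.59, with its other probe set, at 0.35, differing in call, and was not called after quantile normalisation over all arrays (adjusted p = 0.0699). The fat body gene Fbp2 fell by 2.09 (adjusted p = 0.00719), by 0.95 without eGFP replicate 3, and was not called with larval arrays alone (adjusted p = 0.176). The Hox gene Antp had a difference of -0.02 (adjusted p = 0.984).

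In all, 520 probe sets were called in larvae at 29 °C, 260 higher and 260 lower, of which 56 higher and 80 lower changed at least 1.5-fold. The interaction with temperature called 83, and 69 were Ubx-dependent, 28 higher and 41 lower. The Hr3 call was lost without Ubx replicate 1, 2 or 3 (adjusted p = 0.128, 0.217 and 0.135) and without eGFP replicate 1, 3 or 4 (adjusted p = 0.115, 0.0596 and 0.0554), and with larval arrays alone Hr3 had an adjusted p = 0.292. Without eGFP replicate 2 at 19 °C the interaction called 125.

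Larval genes described in the literature as repressed by Ubx in the haltere were lower as a list, with a median of -0.21. Of 8 measured, 4 were called lower (4 adjusted over the list alone). The wing selector gene vg fell by 0.45 (adjusted p = 3.03e-08), the spalt-related gene salr by 0.41 (adjusted p = 1.94e-05) and the vein regulator gene kn by 0.78 (adjusted p = 5.94e-08), the last with probe sets that differed in call. The fourth, salm, fell by 0.24 (adjusted p = 0.0383), a call lost without Ubx replicate 1, 2 or 3 (adjusted p = 0.186, 0.131 and 0.0554), without eGFP replicate 3 or 4 (adjusted p = 0.145 and 0.199), and with arrays centred on their medians (adjusted p = 0.0768). The list test gave an adjusted p = 4.161e-06, and adjusted p = 0.03939 with an estimated correlation. With the preset correlation 5 larval lists were called, and 21 of 35 splits of the same arrays, the real one included, called as many. Chance can therefore not be excluded for the number of larval lists called with that setting. The cell cycle list lay lower with a median of -0.14 (adjusted p = 5.505e-08), with 2 of 29 genes called lower and 8 adjusted over the list alone. Of these 2, aurB at -0.36 kept its call whichever array was left out, while dup at -0.23 (adjusted p = 0.0429) lost it without any of 7 of the 8 arrays (adjusted p from 0.0565 to 0.22). The call of the list was lost at an adjusted p = 0.276 with an estimated correlation.

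Of the Notch target genes in larvae, E(spl)m4-BFM fell by 0.65, a call lost with larval arrays alone at the same difference, and E(spl)mbeta-HLH fell by 0.41. The call of E(spl)m7-HLH, at -0.53, was lost without Ubx replicate 1 (adjusted p = 0.153) or eGFP replicate 1 or 2 (0.053 and 0.0707). That of E(spl)mdelta-HLH, at -0.32, was lost without Ubx replicate 1, 2 or 3 (adjusted p = 0.18, 0.132 and 0.053) or eGFP replicate 1, 3 or 4 (0.0837, 0.0503 and 0.106). The Notch signalling list had 4 of 17 members called lower (1 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.01934, and adjusted p = 0.2947 with an estimated correlation). In the EGFR signalling and vein list the vein gene net fell by 0.78 (adjusted p = 7.66e-06), with 3 of 17 called lower (4 adjusted over the list alone, camera adjusted p = 0.0441, and adjusted p = 0.2947 with an estimated correlation). That list was not called after quantile normalisation over all arrays (adjusted p = 0.05835). In the ecdysone response list Sox14 rose by 0.38 (adjusted p = 8.26e-06) along with Hr3, 2 of 24 called higher (2 adjusted over the list alone). Its camera call (adjusted p = 0.0247, and adjusted p = 0.276 with an estimated correlation) was lost without Ubx replicate 1 (0.05292), Ubx replicate 3 (0.06583) or eGFP replicate 2 (0.0531). In the interaction the ecdysone response list was called higher with both settings (adjusted p = 5.197e-08, and adjusted p = 0.001605 with an estimated correlation). Its median was 0.08 at 29 °C and -0.095 at 19 °C, so lower values of the Ubx line with the transgene off made up part of this. Which part is larger is not settled, since the 29 °C median ran from 0.045 to 0.116 on leaving out single arrays. The interaction also called the Ubx-repressed list lower (adjusted p = 0.0001802) and the cell cycle list lower (adjusted p = 9.151e-09), and the notum list (adjusted p = 0.0001802) and the apoptosis list (adjusted p = 0.006783) higher; these last were not called at 29 °C alone (adjusted p = 0.08127 and 0.05232). None of these 4 was called with an estimated correlation, at adjusted p = 0.09822 for the Ubx-repressed list and 0.1328 for each of the others. The apoptosis list was also not called with the mean of a gene's probe sets (adjusted p = 0.1192).

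**Figure D1:**
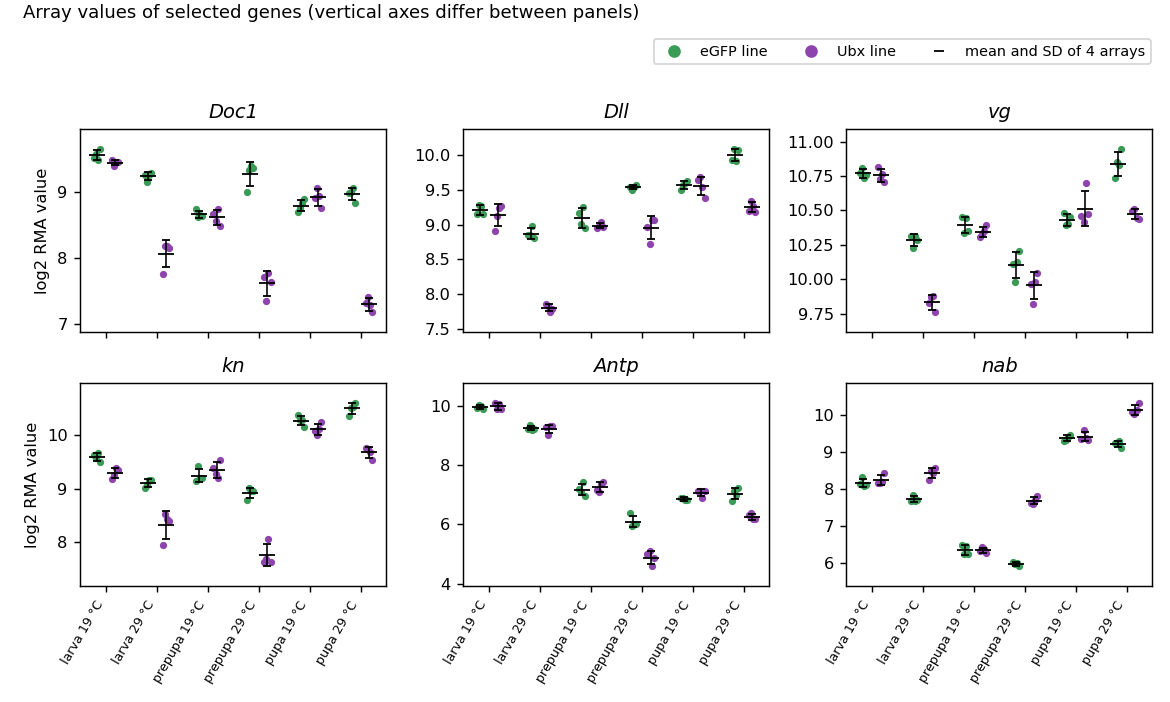
Log2 array values of Doc1, Dll, vg, kn, Antp and nab in the Ubx and eGFP lines at each stage and temperature, with points for arrays and the mean and SD of 4 arrays; vertical axes differ between genes, and levels are not comparable across the 6 sets. Doc1 and Dll lie lower, and nab higher, in the Ubx line at 29 °C at all 3 stages.

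Prepupal wings were compared next, 6 h after puparium formation with the transgene on. The anion transporter gene Esp rose by 3.47 (SE 0.09, adjusted p = 7.27e-31) and daw, which encodes an activin-type ligand, by 3.13 (SE 0.16, adjusted p = 8.93e-20). The secreted glycoprotein gene ana rose by 1.79 (SE 0.09, adjusted p = 1.38e-19). The microtubule protein gene tau fell by 2.16 (SE 0.10, adjusted p = 2.24e-21), the calmodulin-binding protein gene igl fell by 2.06, and the carboxypeptidase gene Nna1 fell by 2.48 (SE 0.17, adjusted p = 2.52e-15). The cuticle gene Cpr50Ca fell by 1.80 and the cytochrome gene Cyp310a1 by 2.22. Antp fell by 1.21 (SE 0.10, adjusted p = 5.73e-13) at this stage, while its other probe sets stood at -0.16 and -0.34 and the probe sets differed in call. The gene nab rose by 1.72, with its other probe set at 0.34, and these too differed in call. Cyp4p2 fell by 5.04 and Cyp4p1 by 3.04, against -4.04 and -2.47 at 19 °C. CG14191 rose by 2.82, CG13833 by 2.62, CG8568 by 2.19, CG5065 by 2.16 and CG15096 by 1.79. CG13033 fell by 1.88, CG13893 fell by 1.86 and CG6462 fell by 1.67. The gene for the signalling adaptor Sarm rose by 2.17 through its brightest probe set, but its 9 probe sets differed in sign, and CG43394 rose by 1.85 with a second probe set at 0.12.

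Of the 3 stages, prepupae had the most calls at 29 °C, 2672, with 1507 higher and 1165 lower, and 192 higher and 212 lower at 1.5-fold or more. The interaction called 1443, 880 higher and 563 lower, and after quantile normalisation over all arrays 715 higher and 725 lower. Ubx-dependent probe sets numbered 1114, 673 higher and 441 lower, and after that normalisation 567 higher and 567 lower.

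Individual wing patterning genes changed in prepupae, but not whole lists in 1 direction. The vein gene kn fell by 1.18 (adjusted p = 1.94e-13, probe sets differing in call) and Dll by 0.58 (adjusted p = 3.56e-08). The glypican gene dlp fell by 1.13 (adjusted p = 3.65e-17) and the Dpp modulator gene magu rose by 0.92 (adjusted p = 1.6e-14). The Iroquois genes caup and ara fell by 0.61 and 0.38. The laminin gene wb fell by 1.03 (adjusted p = 5.97e-15, probe sets differing in call). The cell adhesion gene sns rose by 1.45 (adjusted p = 2.85e-12), with 0.68 at 19 °C, and the sodium pump gene nrv2 by 1.53 (adjusted p = 3.51e-19). The chaperone gene Hsc70-3 fell by 0.65 (adjusted p = 1.64e-11). With camera 0 of 25 lists were called, 3 had an unadjusted p under 0.05, and 0 were called with an estimated correlation. The lowest adjusted p was 0.1057 for the Ubx-repressed list, in which 0 of 8 were called higher and 4 lower (1 and 5 adjusted over the list alone).

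Called members of the other lists in prepupae are given here as higher and lower, with the counts adjusted over the list alone after them. Leaving out single arrays takes some away: over all lists 74 of 101 called genes kept the call whichever array was left out, against 26 of 37 in larvae and 65 of 89 in pupae. The Hox list had 0 and 1 of 4 (0 and 1), wing pouch and hinge identity 3 and 6 of 15 (4 and 6), and anterior-posterior patterning with Hedgehog signalling 3 and 3 of 14 (3 and 4). Dpp signalling had 5 and 4 of 17 (5 and 5), Wingless signalling 1 and 0 of 5 (1 and 0), Notch signalling 4 and 2 of 17 (5 and 3), and EGFR signalling with vein genes 1 and 3 of 17 (1 and 3). The sensory organ list had 1 and 1 of 16 (1 and 1), ecdysone response 2 and 1 of 24 (2 and 1), integrin adhesion and matrix 2 and 3 of 24 (6 and 4), and planar polarity 4 and 2 of 17 (5 and 2). Cell cycle had 0 and 3 of 29 (0 and 3), growth with insulin and Hippo signalling 6 and 4 of 19 (8 and 6), apoptosis 1 and 1 of 14 (1 and 1), and heat shock proteins 1 and 3 of 11 (1 and 3). Cuticle proteins had 9 and 15 of 106 (11 and 18), with Cpr49Ah at 2.16, and immune response genes 0 and 0 of 15 (0 and 0), with 2 at an unadjusted p under 0.05 in limma. Of the lists for other cell types, haemocyte markers had 3 and 0 of 16 (4 and 1; srp and Pvr both lost their calls without Ubx replicate 1 or 4 or eGFP replicate 3, which leaves 1), fat body 0 and 0 of 7 (0 and 0, with 1 at an unadjusted p under 0.05), myoblast and muscle 3 and 1 of 20 (3 and 1), and tracheal 0 and 2 of 13 (1 and 2). Neuron and glia markers had 1 and 1 of 20 (1 and 1), salivary gland 1 and 0 of 10 (0 and 0), and notum with thorax body wall 1 and 3 of 11 (1 and 3).

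**Figure D2:**
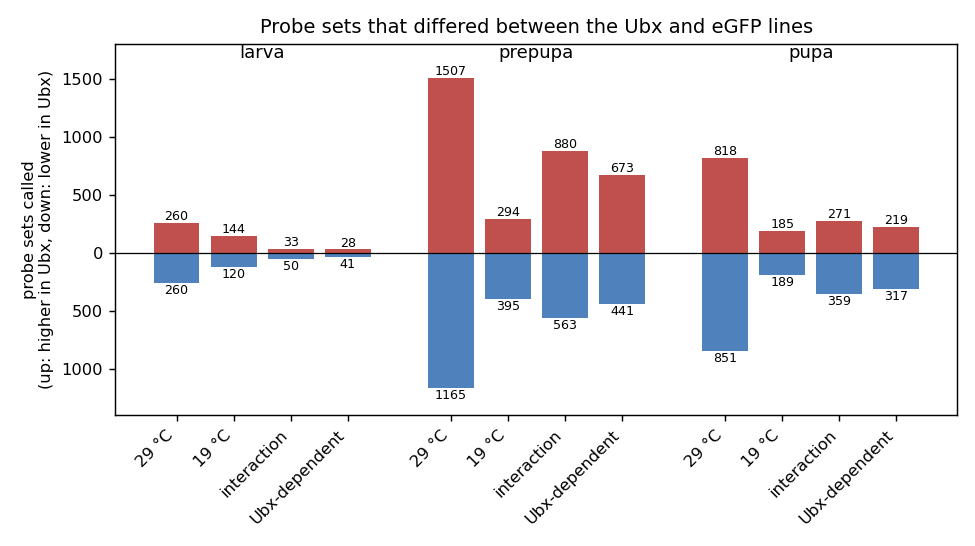
Numbers of probe sets called higher (up) and lower (down) in the Ubx line at each stage, for the 29 °C comparison, the 19 °C comparison, the interaction and the Ubx-dependent set. The 29 °C bars are highest in prepupae (1507 higher, 1165 lower) and lowest in larvae (260 and 260).

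Pupal wings were compared 16 h after puparium formation. The cuticle genes Cpr49Ae and Cpr50Cb rose by 5.13 (SE 0.20, adjusted p = 2.47e-23) and 2.45 (SE 0.11, adjusted p = 2.95e-21), Cpr49Ae from a difference of -1.12 at 19 °C, while Cpr78E fell by 1.72. The eGFP mean of Cpr49Ae at 29 °C, 4.95, lay only 0.54 above the highest array median of its set. Replicate 1 raised it (5.57 against a mean of 4.75 for the others), so the size of this rise is uncertain. The spätzle family ligand gene spz6 rose by 2.75 (SE 0.13, adjusted p = 1.55e-20), the hormone gene Lst by 1.99 and js by 2.54 (SE 0.08, adjusted p = 8.39e-28). The gene for the secreted protein nord fell by 1.97 (SE 0.08, adjusted p = 2.06e-23), Qsox2, for a sulfhydryl oxidase, by 1.88, Trim9, for a ubiquitin ligase, by 1.80, and Doc1 fell by 1.67 (SE 0.09, adjusted p = 1.29e-19). Antp fell by 0.77 (adjusted p = 1.2e-07), with its other probe sets at 0.03 and -0.40, which differed in sign. The driver locus nab rose by 0.93 (adjusted p = 4.71e-13). The largest rise was that of CG4000, by 5.66 (SE 0.21, adjusted p = 5.9e-24); CG10019 rose by 3.08, CG14191 by 1.83 and CG13003 by 1.59. Cyp4p2 fell by 5.32, CG32572 by 3.00 and CG16820 by 2.58, against -4.67, -2.13 and -1.80 at 19 °C, and CG7367 fell by 1.61. The lipophorin receptor gene LpR1 fell by 1.95, with a second probe set at -0.19. The ecdysone-induced gene Eig71Ej rose by 1.49 (adjusted p = 0.00627), a call lost without Ubx replicate 4 (adjusted p = 0.0618), eGFP replicate 2 (0.0846) or eGFP replicate 3 (0.053), and with pupal arrays alone (0.17).

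Pupal calls at 29 °C numbered 1669, 818 higher and 851 lower, of which 168 higher and 182 lower changed at least 1.5-fold. Centring each array on its median gave 516 higher and 1120 lower. The interaction called 630, 271 higher and 359 lower (centred, 188 and 454), and 536 were Ubx-dependent, 219 higher and 317 lower (centred, 153 and 395).

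Several wing vein and patterning genes fell in the pupal Ubx line and a few rose. The intervein gene bs fell by 0.64 (adjusted p = 1.01e-13), kn by 0.82 (adjusted p = 5.55e-09, probe sets differing in call), ara by 0.64 (adjusted p = 5.72e-10), caup by 0.64 (adjusted p = 3.93e-10), Mad, the Dpp effector gene, by 0.56 (adjusted p = 1.23e-08) and Dll by 0.76 (adjusted p = 5.8e-11). The posterior genes en and hh fell by 0.34 and 0.31. The chitin deacetylase genes serp and verm, counted as tracheal but also in the cuticle list, fell by 1.24 (adjusted p = 1.13e-14) and 0.95 (adjusted p = 2.17e-12). Rises included the transcription factor gene dve at 0.73 (probe sets differing in call), the laminin gene LanA at 0.91 and the proneural gene sc at 0.32. The proneural gene ac, at 0.35, was called (adjusted p = 0.0412) but not without Ubx replicate 1, 2 or 3 (adjusted p = 0.0705, 0.0957 and 0.113) or eGFP replicate 1, 3 or 4 (adjusted p = 0.15, 0.0875 and 0.0809), nor with centred arrays (adjusted p = 0.108).

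Of 25 lists in pupae, 6 were called by camera, all of them lower, and 0 with an estimated correlation. An unadjusted p under 0.05 was reached by 8. With the preset correlation, 14 of 35 splits of the same arrays, the real one included, called as many as 6 lists. Chance can therefore not be excluded for this number. Some genes belong to several lists, salr for example to the Ubx-repressed and Dpp lists, so these are not separate results. The anterior-posterior list had 0 higher and 5 lower of 14 (0 and 6 adjusted over the list alone), with adjusted p = 2.433e-05, and adjusted p = 0.06401 with an estimated correlation. EGFR signalling with vein genes had 0 and 6 of 17 (0 and 6 adjusted over the list alone), with adjusted p = 9.977e-05, and adjusted p = 0.06401 with an estimated correlation. The Ubx-repressed list had 2 and 4 of 8 (2 and 5 adjusted over the list alone), with adjusted p = 0.0004458, and adjusted p = 0.08621 with an estimated correlation. Tracheal markers had 2 and 4 of 13 (2 and 5 adjusted over the list alone), with adjusted p = 0.003327, and adjusted p = 0.08896 with an estimated correlation. Dpp signalling had 0 and 5 of 17 (2 and 6 adjusted over the list alone), with adjusted p = 0.007844, and adjusted p = 0.4179 with an estimated correlation. Wing pouch identity had 2 and 7 of 15 (2 and 7 adjusted over the list alone), with adjusted p = 0.0101, and adjusted p = 0.1754 with an estimated correlation. The interaction called these 6 lists lower as well. There the anterior-posterior, EGFR and tracheal lists held at adjusted p = 0.0208 each and the Ubx-repressed list at adjusted p = 0.02408 with an estimated correlation, while Dpp signalling (0.1858) and wing pouch identity (0.1128) did not. It also called immune response genes higher (adjusted p = 0.04249, and adjusted p = 0.4547 with an estimated correlation), with the antimicrobial peptide gene CecB at 1.34 at 29 °C. The cuticle list was not called in pupae at 29 °C, with 12 and 13 of 106 (15 and 15 adjusted over the list alone) and adjusted p = 0.5418.

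Some of these differences, and the comparisons of stages or temperatures that use them, have an uncertain size, because the lower group mean was not shown to be above background: it lay below the highest array median of its set or less than 0.5 above it. At 29 °C these are Hr3, CG10019, Cyp4p1, Vajk3, CG7201 and Fbp2 in larvae, Esp, Nna1, igl, CG6462, Antp, Cyp4p1 and Cyp4p2 in prepupae, and CG10019, Cpr50Cb, CG14191, CG13003, Trim9, Cyp4p2 and CG32572 in pupae. Examples of that mean are 4.28 for prepupal igl, 4.30 for pupal CG10019 and 4.21 for pupal Cyp4p2. At 19 °C they are Cyp4p1 and Cyp4p2 at all 3 stages, mthl8 in larvae and pupae, GstT3 in prepupae, and Fbp2 and CG32572 in pupae. The Ubx mean was the low one at both temperatures for Cyp4p1 in larvae and prepupae, Cyp4p2 in prepupae and pupae, and CG32572 in pupae. For these a Ubx-dependent call does not show a fall when Ubx is switched on.

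To see whether the stages share responding genes, Ubx-dependent probe sets were compared between stages, and 20 were shared by all 3. The named ones lower at every stage were Dll, Doc1, Doc2, Doc3, the Golgi kinase gene fj, nord, CG14301 and CG7367. Named and higher were nab, the leg patterning gene bab2, Ypel, rdo, CG10019 and CG30460. In larvae, for example, bab2 rose by 0.42, rdo by 0.55 and CG30460 by 0.46, while Doc3 fell by 0.57 and fj by 0.66. Larva and prepupa shared 15 higher probe sets against 1 at random (adjusted p = 8.678e-15) and 15 lower against 0.96 (adjusted p = 1.262e-14). Larva and pupa shared 11 higher against 0.33 (adjusted p = 1.148e-14) and 13 lower against 0.69 (adjusted p = 8.208e-14). Prepupa and pupa shared 40 higher against 7.85 (adjusted p = 4.056e-17) and 65 lower against 7.45 (adjusted p = 1.48e-41). These are one-sided Fisher's exact tests over probe sets, which are not independent replicates. The stages also share the estimate of each probe set's spread, so a probe set with a low estimate is more easily called at every stage. The numbers at random do not allow for this. The excess depended on the probe sets included: without the dimmest, both directions together, larva and prepupa shared 32 against 3.99 at random (from 30 against 1.97), larva and pupa 30 against 2.03 (from 24 against 1.02), and prepupa and pupa 126 against 32.76 (from 105 against 15.3).

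The difference between the lines at 29 °C was also compared between stages. The 19 °C difference is not subtracted here and varied by stage as well, for CG16820 from 1.02 in larvae to -1.80 in pupae, so these values are not a measure of Ubx alone. Esp differed between prepupa and larva by 3.44 (SE 0.12, adjusted p = 2.98e-24), daw by 2.77, Vajk3 by 2.72, tau by -2.14, igl by -2.09 and Cpr50Ca by -1.80. Between pupa and larva, CG4000 differed by 5.76, Cpr49Ae by 5.19, Vajk3 by 2.67, js by 2.49, CG16820 by -3.37, Qsox2 by -1.64 and Buffy by -1.62. Between pupa and prepupa, CG4000 differed by 5.72 (SE 0.30, adjusted p = 3.11e-18), js by 2.95 (SE 0.11, adjusted p = 4.32e-24), Lst by 2.60, Esp by -3.43 and daw by -3.32. Called probe sets numbered 1184 for prepupa minus larva (613 higher, 571 lower), 502 for pupa minus larva (269 and 233, centred 167 and 302) and 1857 for pupa minus prepupa (817 and 1040, centred 521 and 1571).

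The lines were also compared with the transgene off at 19 °C, where many differences were called at some stages only. Both cytochrome genes Cyp4p2 and Cyp4p1 were lower in the Ubx line at all 3 stages, in larvae at -4.97 (adjusted p = 7.29e-34) and -3.35 (adjusted p = 4.2e-28). The glutathione transferase gene GstT3 was higher by 1.13, 1.12 and 0.97 in larvae, prepupae and pupae. The receptor gene mthl8 fell by 1.93 in larvae and fell by 2.15 in pupae. Prepupal Cpr49Ah rose by 1.78 (adjusted p = 2.27e-13), Cyp4e1 by 1.54 and CG6870 by 1.37, and CG43103 fell by 3.52 (adjusted p = 5.59e-22). In pupae, the long noncoding RNA lncRNA:CR43242 rose by 1.19 (adjusted p = 9.04e-12), the haemocyte receptor gene NimC1 by 0.89 (adjusted p = 0.000204) and CG8944 by 0.90, while the fat body gene Fbp2 fell by 3.78 (SE 0.49, adjusted p = 8.95e-07). Larval Hr4, at -1.42 (adjusted p = 0.015) with probe sets that differed, was not called without Ubx replicate 1 (adjusted p = 0.211), eGFP replicate 3 (0.214) or eGFP replicate 4 (0.156), nor with larval arrays alone (0.319).

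Called at 19 °C were 264 probe sets in larvae, 689 in prepupae and 374 in pupae, and 81 of them in the same direction at all 3 stages, 36 higher and 45 lower. Calls made at 29 °C were also made at 19 °C in the same direction for 176, 275 and 215 probe sets, and in the opposite one for 2, 46 and 14. Of the Ubx-dependent probe sets, 6, 71 and 31 were called at 19 °C in either direction.

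**Figure D3:**
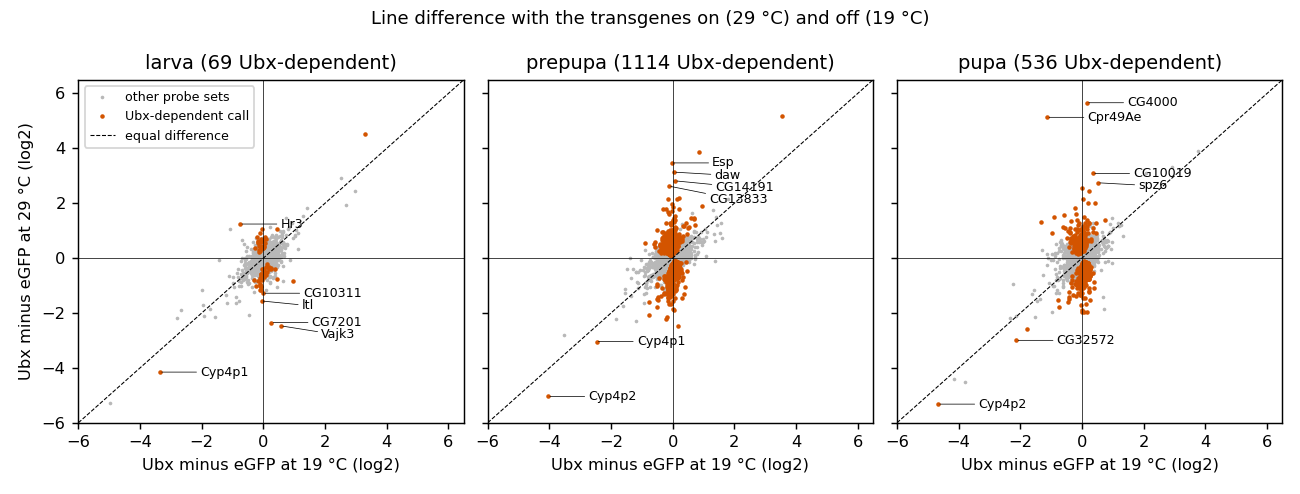
Difference between the Ubx and eGFP lines (log2) at 29 °C on the vertical axis against that at 19 °C on the horizontal axis, a panel per stage and a point per probe set, Ubx-dependent ones in orange and the dashed line marking equal differences. Cyp4p2 and Cyp4p1 are low on both axes, in prepupae at -5.04 and -3.04 at 29 °C and -4.04 and -2.47 at 19 °C. There they lie below the dashed line by an amount called in the interaction, but their Ubx means were near the array medians at both temperatures. For Cyp4p2 these means were 4.89 at 29 °C and 4.99 at 19 °C, and for Cyp4p1 4.79 and 4.52. A fall of the Ubx line with the transgene on is therefore not shown. Prepupal Esp, at 3.47, lies near 0 on the horizontal axis.

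Temperatures and stages in the eGFP line serve as background, and here only genes with the same direction under every scaling are named. Of the cuticle genes, Cpr72Eb rose by 6.14 and Edg91 by 5.03 in prepupae at 29 °C, and Cpr78E fell by 3.88 in prepupae and fell by 3.07 in larvae. Larval Obp99a, an odorant-binding protein gene, rose by 2.75. Pupal yellow-h rose by 3.39 and the lysozyme gene LysX fell by 3.48. From larva to prepupa at 19 °C Osi6 rose by 10.77 and nw fell by 8.38, and from prepupa to pupa Osi6 fell by 10.70 and nw rose by 8.89. No value on a prepupal eGFP array at 19 °C exceeded 14.4, so larval and pupal Osi6 lay below the array medians. The size of its changes is therefore uncertain. Levels of the other genes named here were not checked against the array medians, so their sizes may be uncertain too.

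The temperature comparison called 11993 probe sets in larvae (827 higher, 11166 lower), 10448 in prepupae (7154 and 3294) and 9697 in pupae (8643 and 1054). All probe sets moved together by a median of -0.21, 0.09 and 0.15, and relative to the array medians the calls were 2498 higher and 3139 lower, 4710 and 5742, and 4050 and 3371. Quantile normalisation gave 3066 and 2904, 4928 and 4696, and 3399 and 3524. The stages differed at 14204 probe sets from larva to prepupa (3076 higher, 11128 lower, median -0.26) and 16540 from prepupa to pupa (4527 and 12013, median -0.32). With quantile normalisation these were 5869 and 6735, and 6195 and 6120, and with centred arrays the latter were 7976 and 4739. In each of these comparisons the normalisation set and the condition cannot be told apart, and whether samples taken at the 2 temperatures are of the same developmental age was not tested.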

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

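The tests on Fbp2 and the chromosome shares of the Ubx-dependent sets were chosen only after their results were seen.

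The first pattern is the set of 81 probe sets that differed between the lines at 19 °C in the same direction at all 3 stages. Leaking Ubx expression is argued against, since switching the transgene on left these differences about as they were: the median change in their direction, relative to their size, was -0.059 (quartiles -0.326 and 0.185) where doubling would give 1. Genetic background carried along with the transgenes, which the genotypes place on chromosome 2, is a candidate explanation that passed its test: of 48 named genes with a chromosome, 39 lay there, 81.2 percent against 38.9 percent of 11898 measured genes (one-sided Fisher's exact p = 2.288e-09, adjusted 5.72e-09). Ubx-dependent probe sets showed 57.4 percent in larvae (31 of 54, adjusted p = 0.008988), 38.7 percent in prepupae and 37.6 percent in pupae. Some larval Ubx-dependent calls may therefore carry a background difference that varies with temperature, which stays open.

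The second pattern is a 29 °C difference that could reflect Ubx wings of another developmental age, scored with 200 rising and 200 falling genes of the eGFP line. In pupae 51.2 percent of the Ubx-dependent calls of at least 1.5-fold went the way of the score (111 of 217, 95 percent interval 44.3 to 58). The score differed there by -0.019 (exact permutation p = 0.7714). This share lies below the 60 percent that was set beforehand for the explanation. With so small a score difference the direction counted is close to arbitrary, so the share does not decide. The interval counts probe sets measured on the same arrays as independent and may be too narrow. Larvae (-0.032, exact permutation p = 0.2, 47.4 percent, 18 of 38, interval 31 to 64.2) and prepupae (0.146, exact permutation p = 0.2857, 56.3 percent, 151 of 268, interval 50.2 to 62.4) stay open too, and their intervals include that 60 percent. That the scores missed the smallest p does not decide at any stage, since with 4 against 4 arrays such a p does not show equal scores. The prepupal score differed about as much with the transgene off (0.128, exact permutation p = 0.0286, the smallest that 4 against 4 arrays can give, adjusted 0.1713), with all 4 Ubx arrays above all eGFP arrays, and its 0.146 at 29 °C is 1.6 percent of the change between stages. The lower larval cell cycle list was not a standing line difference (median 0.014 at 19 °C against -0.14 at 29 °C), nor due to a single array (highest adjusted p without any 1 of the 8 arrays 2.507e-05), and an effect of Ubx on it stays untested beyond the comparison itself, whose adjusted p over the alternatives ran from 6.903e-10 to 0.276, the latter with an estimated correlation.

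The third pattern is Fbp2, lower in pupal wings of the Ubx line by -3.78 at 19 °C (means 4.37 and 8.15) and -4.52 at 29 °C (4.99 and 9.52), the 19 °C size being uncertain because 4.37 is near the array medians and not shown to be above background. Less fat body RNA in these pupal samples is argued against, since the other abundant markers Lsp2, Fbp1 and apolpp (eGFP means 12.43, 9.52 and 11.36 at 19 °C) had a median of only -0.216 over both temperatures, with 19 °C values of -0.61, -0.56 and -0.49, 29 °C values of 0.06, 0.27 and 0.30, and SEs from 0.53 to 0.68. A background difference at the gene itself could also be the source: Fbp2 lies on chromosome 2 (value 1 for yes), and 1 gene decides nothing, so this stays open. In larvae at 29 °C Fbp2 was lower as well (-2.09, adjusted p = 0.00719), with the fat body list at a median of -0.546 (camera adjusted p = 0.05709) and -0.921 in the interaction (0.1742), and less fat body RNA there was not tested and stays open. No biological explanation was tested.

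Other splits of the same arrays were counted for each result. For the lines at 29 °C the real grouping alone (1 of 35 splits) gave as many calls: 520, 2672 and 1669 in larvae, prepupae and pupae against at most 26, 442 and 698. At 19 °C it was again 1 of 35 (264, 689 and 374 against at most 6, 169 and 82), as for the temperatures (11993, 10448 and 9697 against 1333, 4402 and 2798) and the stages (14204 and 16540 against 8969 and 11584). No other split gave as many, so chance is unlikely for these, but 1 of 35 is the lowest share these splits allow. Splits that mix the lines also turn line differences into spread within groups, which itself lowers their counts. For the interaction 4, 2 and 3 of 100 splits gave as many (83, 1443 and 630, highest other 302, 1828 and 760), and for the Ubx-dependent set 3, 3 and 4 (69, 1114 and 536, highest other 176, 1572 and 678). For the differences between stages it was 3, 3 and 2 of 100 (1184, 502 and 1857, highest other 1201, 572 and 1953). At most 4 of 100 splits gave as many, so chance is unlikely here too but not excluded, with no adjustment over these results. The larger splits, such as the 302 in larvae, several times the real count, all kept a real grouping of the lines at 1 temperature or stage, so that line differences no longer cancelled; splits that mixed both gave at most 49, 92 and 311 for the interaction, 10, 37 and 168 for the Ubx-dependent set, and 40, 18 and 145 between stages. For the number of gene lists called at 29 °C chance cannot be excluded in larvae and pupae, since 21 and 14 of 35 splits gave as many as the real 5 and 6, with 10 and 16 the highest other. In prepupae the real number is 0, so all 35 splits give as many by construction (highest other 2) and nothing follows.

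Single arrays stood apart in 9 of 114 groups of a named gene and 2 of 36 array measures, where chance gives about 5 percent of groups. Their gap to the nearest array as a share of the group's range exceeded Dixon's 95 percent critical value for 4 arrays. Among larval arrays at 29 °C, Hr3 in Ubx replicate 4 was at 3.55 against a mean of 5.76 for the others (0.852), and nab in eGFP replicate 2 at 7.85 against 7.68 (0.862). CG7201 in larval Ubx replicate 2 was at 3.99 against 4.22 (0.896), and Doc1 in larval Ubx replicate 1 at 7.76 against 8.18 (0.931). In prepupae at 29 °C, CG13833 in eGFP replicate 2 was at 5.93 against 6.19 (0.865), CG8568 in eGFP replicate 1 at 8.37 against 7.98 (0.921) and ana in eGFP replicate 1 at 7.39 against 7.13 (0.883). In pupae at 29 °C, CG4000 in eGFP replicate 1 was at 7.13 against 5.3 (0.953) and Cpr78E in Ubx replicate 1 at 9.33 against 8.91 (0.917). For whole arrays, the upper quartile of prepupal eGFP replicate 3 at 19 °C was 7.38 against 7.31 (0.922). Larval eGFP replicate 1 at 19 °C stood apart by the highest correlation with the rest of its group, 0.99902 against 0.99851 to 0.99859 (0.843).

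The difference between the lines at 29 °C, with that at 19 °C not subtracted, changed between stages by a direct test at 1184, 502 and 1857 probe sets, and for js the pupal difference exceeded the prepupal one by 2.95. Among the array controls left out of the tests, a pair of probe sets whose targets are not given in the sources used here was high only in the eGFP line at 29 °C, where eGFP is expressed. The larger difference, Ubx minus eGFP, was -8.64 in larvae, -8.95 in prepupae and -9.08 in pupae, and is a high value of the eGFP line rather than a fall in the Ubx line. Their means there were 11.35 to 12.47 in the eGFP line and 3.03 to 3.56 in the Ubx line, near the lowest values of the arrays, so the exact size is uncertain. At 19 °C both lines were near those lowest values too (2.76 to 3.36), with differences of -0.01 to -0.06 that were not called. With this pair included, 2 of the 183 array controls were called at 29 °C in larvae, 17 in prepupae and 5 in pupae. Only the pair differed 2-fold or more in any set, and why the others differed was not tested.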

How the results depend on the processing

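The sets without 19 °C calls and without the farthest array were chosen after seeing the data. Of 322 pairs of a named gene and a comparison, 1 probe set per gene kept all 322 on their side of the threshold. That setting keeps the probe set through which each gene was named, so little could change. Leaving out the dimmest probe sets kept all of the 317 whose probe set stayed in. Calls were lost for 100 under the fold threshold, 45 on leaving out single arrays, 31 with the arrays of the named stages alone, 14 with centred arrays, 7 with quantile normalisation, 6 with the replicate block and 2 with the other variance model.

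With the 1.5-fold threshold added, the larval, prepupal and pupal counts became 136, 404 and 350 at 29 °C, 75, 123 and 92 at 19 °C, 49, 364 and 279 for the interaction, 38, 268 and 217 for the Ubx-dependent set, and 861, 3017 and 1255 for temperature. The stage differences became 381, 229 and 472, the successive stages 7296 and 7504, and the overlaps of stages 13, 13 and 45, from 30, 24 and 105. A stricter threshold can only lower these. With the arrays of the named stages alone, the interaction called 948 in prepupae and 398 in pupae, and 19 °C pupae 212, with fewer arrays behind the spread. The larval temperature count became 6879 without the dimmest probe sets and 7432 with 1 probe set per gene, where fewer are tested, and 5637 with centred and 5970 with quantile-normalised arrays, where the common shift is removed. From prepupa to pupa the count became 9838 without the dimmest and 10532 with 1 probe set per gene. Overlaps of all 29 °C calls, a wider set by construction, were 235, 273 and 487.

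With an estimated correlation the lists called at 29 °C numbered 1 in larvae (from 5) and 0 in pupae (from 6), and in the interaction 1 in larvae (from 5) and 4 in pupae (from 7). After quantile normalisation 1 list was called in prepupae at 29 °C (from 0); the cause was not tested. The larval difference of Antp, -0.016 and not called, turned to 0.054 on leaving out 1 array.

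Leaving out single arrays, the 29 °C counts ranged from 406 to 550, 2220 to 2690 and 1294 to 1812, the 19 °C counts from 215 to 279, 513 to 759 and 284 to 370, and the interaction from 61 to 125 (125 without larval 19 °C eGFP replicate 2), 1125 to 1515 and 503 to 760. The Ubx-dependent set ranged from 51 to 97, 923 to 1122 and 438 to 628, and the stage differences from 982 to 1224, 390 to 540 and 1424 to 2231. Temperature ranged from 11129 to 11464, 9924 to 10045 and 9010 to 9209, and the stages from 13775 to 13966 and 16252 to 16439.

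Replicate numbers did not clearly pair the arrays: same-numbered arrays correlated from -0.145 to 0.361, with 12 of 48 pairs over 0.1 and 15 of 48 best with their own number. In larvae 2 or 3 of 4 arrays were best with their own number in each comparison, against 0 to 2 at the other stages. Pairing of the larval arrays is therefore not excluded. The replicate block gave 502, 2611 and 1637 calls at 29 °C, 257, 682 and 378 at 19 °C, 74, 1429 and 637 in the interaction and 63, 1100 and 546 Ubx-dependent, with 8 lists called in larvae at 29 °C (from 5). Without probe sets called at 19 °C the Ubx-dependent set held 63, 1043 and 505, and without the farthest array of each group 438, 2134 and 1419 were called at 29 °C. Signal over background was not given in the sources used here, so what dim signal limits was approached only by leaving out the dimmest probe sets.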

Other observations

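The tests of symbol families below were chosen after their values were seen, 36 of them over families and stages.

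Members of the Vajk family of cuticle genes were Ubx-dependent at each stage. Of 4 measured, Vajk2 and Vajk3 were Ubx-dependent and lower in larvae, at -0.83 and -2.47, against 0.96 and 0.58 at 19 °C (two-sided Fisher's exact p = 0.0001189, adjusted 0.00428). In prepupae Vajk1 stood at 0.46 and in pupae Vajk2 at 1.40, both higher, while 1 member was called lower at 29 °C at each of these stages, and the family tests did not pass (adjusted p = 0.5749 and 0.4401). Of 66 Cpr cuticle genes, 9 were Ubx-dependent in pupae, 6 higher and 3 lower (two-sided Fisher's exact p = 0.0009711, adjusted 0.01748), Cpr100A among the lower at -1.09, and 3 in larvae (adjusted p = 0.03888).

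The odorant-binding protein gene Obp56a had a pupal difference of 1.32 at 29 °C and -1.31 at 19 °C. Unnamed probe set 1633998_s_at was higher in the Ubx line with the transgene on (4.53, 5.18 and 3.91 in larvae, prepupae and pupae) and off (3.30, 3.55 and 3.75). Unnamed probe set 1624393_at was higher at all 3 stages with the transgene on (0.65, 1.66 and 1.00) and lay at -0.02, -0.14 and 0.02 with it off.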
